A study of Mus musculus with 12 samples.

How the data were processed

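Total RNA from mouse embryonic fibroblasts without their own PPARγ, into which wild-type or S273A PPARγ had been introduced, was labelled with biotin and measured on Affymetrix arrays. There were 12 arrays in 4 groups of 3: wild-type, S273A, wild-type with 1 µM rosiglitazone and wild-type with 1 µM MRL24, both for 24 h. The sample titles call the S273A cells mutant and the series text names the substitution, which was taken as the same group. The authors deposited the values as intensity on a linear scale, already brought to near-identical distributions; how they were normalized is not given in the sources used here. Array medians lay between 297 and 315, and values at the floor of 1 made up 2.09% to 2.47% of an array. Every column of values was used.

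Of 22690 probe sets, 64 were controls, 20380 carried 1 gene symbol, 691 several and 1555 were not named here. Symbols were looked up by Entrez ID for 20351 probe sets and none changed. Each of 12393 genes was represented by its brightest probe set. Genes whose mean lay under the 30th percentile, an intensity of 98.7, were left out, which left 9154. Values were used as log2(value + 16), so fold changes of dim genes are understated. Mean ± SD in the text are of intensities, and log2 changes and folds are of the transformed values.

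All 12 arrays were fitted in 1 model with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on the mean level). It left 8 residual degrees of freedom, with 7.72 prior degrees of freedom and a median residual SD of 0.101 on the log2 scale. The 4 comparisons were S273A, rosiglitazone and MRL24 each against untreated wild-type, and rosiglitazone against MRL24. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Tables and figures used python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The 4 comparisons with their tests, the covariance of shared changes, the lists, the rule for named genes and the alternatives named at the end were fixed before the data were examined. The counts over splits of the arrays, the contrasts of the ligand groups with S273A, the number of shared genes without single untreated arrays, the lists of matched length from simulated groups and the medians of gene families without single arrays were chosen after results had been seen.

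Of 31 lists, the 29 with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Each was also tested with fry, which asks whether a list's genes move on balance one way and compares them with no other genes. Members were also counted as called over all genes and when adjusted over the list alone. Members without a usable probe set or below the filter were not tested. This left 25 of 44 agonist targets, 11 of 24 thermogenic genes and 5 of 13 macrophage markers. The lists were the study's Ser273 signature, PPARγ agonist targets, thermogenic genes, adipokines, adipocyte transcription factors, fatty acid and triglyceride synthesis, lipid droplet and lipolysis, fatty acid oxidation, oxidative phosphorylation, tricarboxylic acid cycle and pyruvate metabolism, glycolysis and glucose uptake, cholesterol synthesis and uptake, circadian clock, glucocorticoid response, extracellular matrix and fibroblast, cytoskeletal and myofibroblast, inflammatory and NF-κB, interferon response, mitotic cell cycle, unfolded protein response, heat shock, oxidative stress, hypoxia and p53 targets. There were also markers of skeletal muscle, macrophages, endothelium, chondrocytes, osteoblasts, epithelium and neural cells. In every shifted list the median, the mean and the test had the same sign.

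Genes were named by rule: in each comparison the 10 called genes with the largest rise and the 10 with the largest fall among those whose 3 arrays in one group all lay above the 3 in the other; Pparg; the Ser273 signature; up to 4 called members of each list described; and control genes. Fewer are described than the rule allows, and those were picked after their values were seen, partly for keeping their call without single arrays.

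Because 3 comparisons share the untreated arrays, the covariance of their changes was set against that of simulated unchanged groups, with 100 draws per simulation. The first simulation drew residual arrays with replacement. The other simulations, residual arrays permuted over the groups and genes drawn independently with the spread of each group, were added after the values of the first had been seen, and all 3 are reported. Drawing genes independently makes the simulated spread too narrow. Most draws gave few calls, with a median of 0 to 4 per comparison although single draws reached 822, so lists as long as the observed ones were also taken from each draw by smallest p. These treat every listed gene as noise.

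The procedure was tested on simulated data with 50 changed genes per size among 9154. It recovered 19 at a log2 change of 0.25, 38 at 0.5, 49 at 1 and 50 at 2, and 11 of 167 calls (6.6%) were false. Genes were drawn independently, with the same spread in every group and no outlying array. The 6.6% therefore checks the procedure and does not give the share of false calls in the real data.

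Alternatives were quantile normalization, median scaling, no filter or a 50th percentile filter, the mean of all probe sets of a gene, log2 of the value plus 1 or 64, no mean trend, only the 2 groups compared, array weights, a replicate block, an estimated correlation, and leaving out each array in turn.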

Results

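Gene expression was measured on 12 arrays in mouse embryonic fibroblasts that lack their own PPARγ, the nuclear receptor that drives fat cell differentiation. The cells carried either wild-type PPARγ or S273A, a form in which alanine replaces the serine at position Ser273, a phosphorylation site of the receptor. RNA was taken after 6 days of differentiation. Wild-type cells were also exposed for 24 h to 1 µM rosiglitazone, a thiazolidinedione and full agonist of the receptor, or to 1 µM MRL24, another PPARγ ligand. Each of the 4 groups had 3 arrays, so the number of arrays limits the precision, and an exact test of 3 against 3 arrays cannot give a p below 0.1. The sample labels do not say whether untreated cells received vehicle, or whether the arrays of a group came from separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical.

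Array medians lay between 297 and 315 intensity units, and 2.09% to 2.47% of the values of an array sat at the floor of 1. Untreated wild-type replicate 2 stood apart from the other 11 arrays. Its score on the first principal component, which held 24.5% of the variance, was -17.25, against -5.57 to 8.41 on the others. Its residual SD was 0.148 on the log2 scale, against 0.095 to 0.124. All 3 comparisons with untreated wild-type cells use this array.

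Pparg itself read 904 ± 97.7 in wild-type and 1073 ± 162 in S273A cells (intensity, mean ± SD, n = 3), a log2 difference of 0.24 (SE 0.10, adjusted p = 0.177). It read 833.5 ± 76.1 with rosiglitazone and 846 ± 20.7 with MRL24, and neither ligand passed the test (adjusted p = 0.545 and 0.627). Where its probes lie in the deleted or the introduced sequence was not analysed here, so these levels do not check the labels. The control genes Actb, Hprt and Tbp, read here as housekeeping genes, differed by -0.18 to 0.13 on the log2 scale from untreated wild-type cells and none passed the test. Actb, at a mean of 14.77 on that scale, lay near the array maximum, where intensities may understate a change. A second Actb probe set, at 12.74, differed by 0.08 to 0.14.

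The first comparison set S273A against wild-type cells without ligand, to ask which genes differ when Ser273 of PPARγ is replaced. As far as the labels say, each form was present in 1 set of cells. An effect of S273A and a difference between the cell populations therefore cannot be told apart for any gene or list below. S100a8, a calcium-binding protein of myeloid cells, rose from 558 ± 105 to 1323 ± 20.0 (log2 change 1.24, SE 0.10, adjusted p = 2.89e-06, n = 3). Cd36, a fatty acid transporter and classic PPARγ target, rose from 164 ± 13.2 to 302 ± 26.4 (adjusted p = 1.66e-05), and the lysosomal macrophage marker Cd68 from 556.5 ± 37.0 to 869.7 ± 11.4 (adjusted p = 4.67e-05). Fem1b, a substrate receptor of a ubiquitin ligase, fell from 2293.5 ± 57.5 to 1240.2 ± 22.6 (adjusted p = 1.99e-08). The desmosome protein Pkp1 fell by 0.99 on the log2 scale, the pro-apoptotic BH3 protein Bcl2l11 by 0.73 and the matrix protein periostin (Postn) by 0.69. A second probe set of Fem1b fell by 0.25, and the 4 other Bcl2l11 probe sets changed by -0.17 to -0.50. Other genes that rose were the cytokine gene Il13 (1.72-fold) and Ankrd33b (1.5-fold), and others that fell were the small GTPase Rhoj (1.63-fold), the zinc finger transcription factor Egr2 (1.61-fold) and the magnesium transporter Slc41a2 (1.60-fold).

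In limma's test with Benjamini-Hochberg adjustment, 652 of 9154 genes changed with S273A, 193 higher and 459 lower, with a median absolute log2 change of 0.30. S100a8 was the 1 gene that passed 2-fold. For 22.6% of the tested genes the 3 arrays of one group all lay above those of the other, where chance gives 10%. Without S273A replicate 2 the count was 424, and without S273A replicate 3 it was 390. A fit to the 6 arrays of these groups alone gave 238.

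The list of genes that the study linked to Ser273 was recalled from the published work and held 17 genes, 15 of them on the array. Of the 13 that were tested, 5 rose with S273A and none fell, and 6 rose when adjusted over the list alone. The listed genes were chosen on these samples, so neither count is independent evidence. For Nr3c1, where the probe set used changed by -0.008, others changed by -0.288 and 0.335. Cyp2f2, a cytochrome P450, rose from 538.5 ± 39.7 to 856 ± 39.9. Nr1d1, which encodes the clock repressor REV-ERBα, rose from 1877 ± 166 to 2689.8 ± 62.5, and Txnip, a thioredoxin-binding regulator of glucose uptake, from 5929.9 ± 94.0 to 8317 ± 296. Rarres2, which encodes the adipokine chemerin, rose by 0.56 and the selenium-binding protein Selenbp1 by 0.45 on the log2 scale. Adiponectin (Adipoq), a fat cell hormone, was below the intensity filter and not part of the count, at 53.5 ± 14.1 in wild-type and 97.2 ± 7.9 in S273A cells (adjusted p = 0.0703 without the filter).

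Of the 25 tested targets of PPARγ agonists, 2 rose and 3 fell with S273A (3 and 3 when adjusted over the list alone), and the list as a whole did not shift (camera adjusted p = 0.322). Cd36 rose, while Angptl4, a secreted inhibitor of lipoprotein lipase, fell from 3061 ± 128 to 2257 ± 64.8. Pdk4, a kinase that inactivates pyruvate dehydrogenase, fell from 1469 ± 147 to 1106 ± 15.4. The mean over both Angptl4 probe sets, of which 1 lay below the filter, gave -0.09 (adjusted p = 0.805). Fabp4, the fatty acid carrier of fat cells, differed by 0.03 (SE 0.05). None of 25 fatty acid oxidation genes changed with S273A (camera adjusted p = 0.913), with unadjusted p under 0.05 for 3.

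Interferon response genes fell with S273A: 8 of 20 were lower and none higher, or 9 lower and 1 higher when adjusted over the list alone (camera adjusted p = 5.74e-05). Bst2, a membrane protein that tethers budding virus, fell from 1995 ± 142 to 1408 ± 125, and Usp18, a brake on interferon signalling, fell by 0.52 on the log2 scale (SE 0.09). The guanylate-binding protein Gbp3 also fell by 0.52 (SE 0.11). Of 16 genes of cholesterol synthesis and uptake, 2 rose (4 when adjusted over the list alone) and the list shifted up (camera adjusted p = 4.51e-05), with the sterol oxidase Msmo1 higher by 0.44 (SE 0.05). The shifts of the Ser273, interferon and cholesterol lists held with an estimated correlation (adjusted p = 0.0181, 0.0221 and 0.0221).

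Of 32 extracellular matrix and fibroblast genes, 12 fell with S273A, 2 rose and 18 were not called, or 12 fell and 3 rose when adjusted over the list alone. The list's median log2 change was -0.06, with 13 of 32 above 0. Postn fell, as did the growth factor receptor Pdgfra (-0.64, SE 0.06) and the protease inhibitor Timp3 (-0.60, SE 0.05), and the stromelysin Mmp3 rose (0.46, SE 0.09). A second Pdgfra probe set and 1 of 3 further Timp3 probe sets each changed by only -0.03. The list shifted down (camera adjusted p = 0.0112), but adjusted p = 0.544 with an estimated correlation, and the shift missed the threshold without untreated wild-type replicate 1 (0.0927) or 3 (0.0504). Cytoskeletal and myofibroblast genes gave 3 lower and 1 higher of 18 (5 and 2 when adjusted over the list alone), with the connective tissue growth factor Ccn2 lower by 0.52 (camera adjusted p = 0.0423). That shift had adjusted p = 0.365 with an estimated correlation, and it was lost without any 1 of 6 arrays: wild-type replicate 1 (0.192) or 3 (0.0869), S273A replicate 1 (0.0746) or 3 (0.0733), rosiglitazone replicate 1 (0.0557) and MRL24 replicate 1 (0.0513). It was also lost with the 50th percentile filter (0.122), the mean of all probe sets (0.0903) and a replicate block (0.0541). Mitotic genes shifted down (camera adjusted p = 0.0188) with 2 of 38 lower, or 1 when adjusted over the list alone. Of these, the proliferation marker Mki67 fell from 550.0 ± 22.0 to 407 ± 42.8. This list had adjusted p = 0.365 with an estimated correlation, 0.0901 with the 50th percentile filter, 0.0682 without wild-type replicate 1 and 0.0746 without S273A replicate 1.

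**Figure D1:**
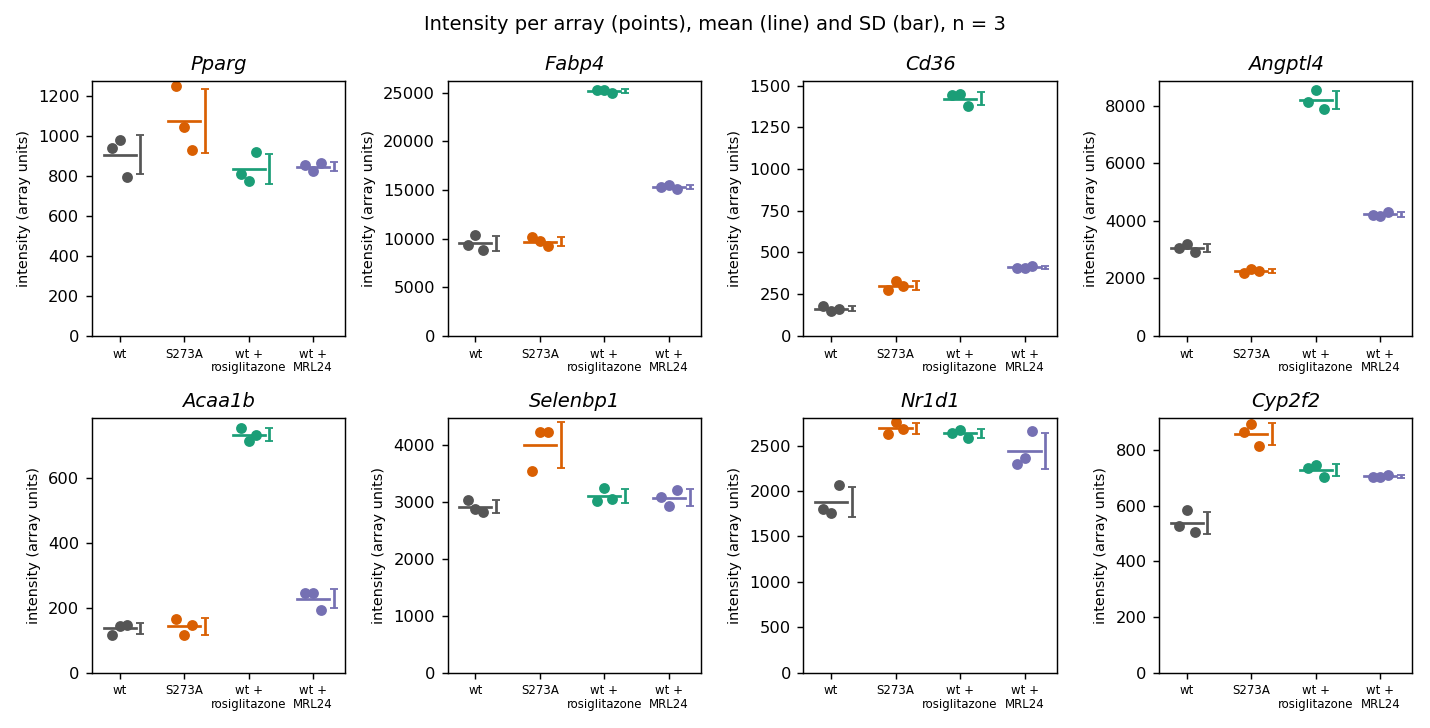
Intensity in array units (vertical axes, from 0) of 8 genes in the 4 groups, with 1 point per array, a line at the mean and a bar for the SD (n = 3). Selenbp1 was raised in S273A cells, at 3995 against 2911 in wild-type cells and 3103 and 3074 with the ligands, whereas Fabp4, Cd36, Angptl4 and Acaa1b were highest with rosiglitazone.

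The second comparison asked what the full agonist rosiglitazone changed in cells with wild-type PPARγ. Cd36 rose 8.02-fold, from 164 ± 13.2 to 1422 ± 40.0 (log2 change 3.0, SE 0.08, adjusted p = 9.45e-13, n = 3). Acaa1b, a peroxisomal thiolase of fatty acid oxidation, rose from 136 ± 16.2 to 736 ± 19.5. Angptl4 rose from 3061 ± 128 to 8200.4 ± 324 and Fabp4 from 9509 ± 782 to 25153 ± 209. Fabp4 then lay near the array maximum of 31882 to 33624, where intensities may understate a change. The ankyrin-repeat protein Kank3 rose 3.06-fold, the imprinted retrotransposon-derived gene Peg10 3.0-fold and the mast cell tryptase Tpsab1 2.51-fold. Among genes that fell, the neutrophil chemokine Cxcl5 went from 515 ± 23.8 to 265 ± 31.6, the synuclein Sncg from 200.1 ± 46.5 to 98.7 ± 6.0, the small proteoglycan Ogn from 301 ± 61.2 to 172 ± 9.2 and the retinoic acid carrier Crabp1 from 957 ± 90.4 to 602 ± 48.5. A second Ogn probe set changed by -0.29.

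With rosiglitazone, 721 of 9154 genes changed in limma's test, 339 higher and 382 lower, and the 9 that passed 2-fold all rose. For 25.5% of the genes the 3 arrays of each group did not overlap, where chance gives 10%. The count fell to 384 without rosiglitazone replicate 2 and to 355 in a fit to the 6 arrays of these groups alone.

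Of 25 tested agonist targets 12 rose and none fell, or 15 when adjusted over the list alone (camera adjusted p = 3.37e-15). Besides Cd36, Acaa1b, Angptl4 and Fabp4, these included Pdk4 (0.93, SE 0.07), lipoprotein lipase (Lpl, 0.83, SE 0.06) and the lipid droplet coat protein Plin2 (0.61, SE 0.04). Of 25 fatty acid oxidation genes 9 rose and none fell, or 14 when adjusted over the list alone (camera adjusted p = 1.97e-09). The mitochondrial trifunctional protein subunit Hadhb rose by 0.44, the thiolase Acaa2 by 0.41 and the very long chain dehydrogenase Acadvl by 0.38. Of 23 genes of the tricarboxylic acid cycle and pyruvate metabolism 4 rose, or 5 when adjusted over the list alone (camera adjusted p = 0.00358). They included pyruvate carboxylase (Pcx, 0.66), the isocitrate dehydrogenase subunit Idh3a (0.60) and Pdk4, which inhibits entry into the cycle. Other Idh3a probe sets changed less, down to 0.17. Of the 13 Ser273 genes 8 rose, or 10 with 1 lower when adjusted over the list alone, which is not independent evidence for the reason given above (camera adjusted p = 2.91e-11). By the probe sets used, their highest change was in Peg10 (1.585) and the others included Nr1d1, Cyp2f2 and Txnip. A second Car3 probe set rose by 2.411, against 0.769 for the one used. Adiponectin, below the filter, read 139 ± 4.8 (adjusted p = 0.00507 without the filter), and the lipid droplet protein Cidec read 97.5 ± 18.8 against 18.4 ± 12.8 (0.00272).

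Of 16 cholesterol genes 4 rose with rosiglitazone, or 5 when adjusted over the list alone (camera adjusted p = 0.00123), with Msmo1 higher by 0.32 (SE 0.05). As with S273A, part of this rise may come from the shared untreated arrays. The agonist target, fatty acid oxidation, tricarboxylic acid, Ser273 and cholesterol shifts held with an estimated correlation (adjusted p = 0.00488, 0.00681, 0.0474, 0.00444 and 0.0433). In fatty acid and triglyceride synthesis 4 of 20 rose, or 6 when adjusted over the list alone, among them ATP citrate lyase (Acly, 0.61, SE 0.06) and the acyltransferase Dgat2 (0.47, SE 0.06). That shift (camera adjusted p = 0.00123) had adjusted p = 0.0688 with an estimated correlation. Of 12 lipid droplet and lipolysis genes 4 rose, or 6 when adjusted over the list alone, among them Plin2 and hormone-sensitive lipase (Lipe, 0.41, SE 0.09). That shift (camera adjusted p = 0.00131) had adjusted p = 0.242 with an estimated correlation.

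Inflammatory and NF-κB genes went the other way: 4 of 20 fell and none rose, or 4 and 1 when adjusted over the list alone. The 4 were Cxcl5, the acute-phase proteins lipocalin 2 (Lcn2, -0.54, SE 0.05) and Saa3 (-0.37, SE 0.03), and the monocyte chemokine Ccl2 (-0.34, SE 0.04). The downward shift (camera adjusted p = 0.0116) had adjusted p = 0.0633 with an estimated correlation. In this list 4 fell and 1 rose with MRL24, 3 fell and 2 rose with S273A, and 3 were lower with rosiglitazone than with MRL24. Camera called none of these 3 shifts (adjusted p = 0.126, 0.506 and 0.0632), while fry called each as lower (adjusted p = 0.0136, 0.033 and 0.0046). The glycolysis list shifted up (camera adjusted p = 0.0116) although its 1 changed member of 21, hexokinase 2 (Hk2), was lower by 0.24, over all genes and over the list alone. Its shift had adjusted p = 0.479 with an estimated correlation, 0.0663 with array weights and 0.207 without untreated wild-type replicate 2. The call of Hk2 was lost without wild-type replicate 1 (0.0565) or rosiglitazone replicate 2 (0.0554) or 3 (0.0635). Hypoxia genes, with 2 of 17 higher by either adjustment, shifted up (camera adjusted p = 0.0137), with adjusted p = 0.479 with an estimated correlation, 0.0663 with array weights and 0.101 after quantile normalization. The prolyl hydroxylase Egln3 rose in this list by 0.30 (SE 0.05), although a second probe set rose by 0.03.

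The third comparison gave the changes with MRL24 at the same dose and time. Cd36 rose 2.38-fold, from 164 ± 13.2 to 411 ± 9.3 (log2 change 1.25, SE 0.08, adjusted p = 6.04e-07, n = 3), and Fabp4 rose from 9509 ± 782 to 15339 ± 199 (adjusted p = 8.27e-07). Angptl4 rose from 3061 ± 128 to 4234 ± 82.7, Txnip from 5929.9 ± 94.0 to 7526 ± 107.5, and the p53-responsive cyclin Ccng1 from 2654 ± 302 to 3737 ± 74.6. Of 2 further Ccng1 probe sets, 1 rose by only 0.09, and the mean over both Angptl4 probe sets was 0.21 (adjusted p = 0.413). The NADPH oxidase subunit Cybb rose from 71.1 ± 9.7 to 152 ± 15.3. The interferon-inducible gene Ifi27l2b fell from 805 ± 81.2 to 528 ± 54.6 and the splicing factor Scnm1 from 322 ± 5.4 to 224 ± 9.9. B3gat1, a glucuronyltransferase, read 149 ± 138 untreated and 1745 ± 507 with MRL24 (log2 change 4.13, SE 0.98, adjusted p = 0.0265), while its other probe sets, both below the filter, changed by -0.24 and -0.10. Its arrays scattered widely, with 1 untreated array at the floor of 1, and the call was lost without wild-type replicate 2 (0.0986) or MRL24 replicate 1 (0.058), 2 (0.0823) or 3 (0.0964).

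With MRL24, 503 of 9154 genes changed in limma's test, 293 higher and 210 lower, and the 4 that passed 2-fold all rose. The split turned with the scaling: after setting all arrays to the same median, 208 of 678 changed genes were higher and 470 lower, and quantile normalization gave 251 and 314. For 29.1% of the genes the 3 arrays of each group did not overlap, where chance gives 10%. The count rested on single arrays more than the others did. It was 818 without wild-type replicate 1, 157 without wild-type replicate 2, and 162, 130 and 76 without MRL24 replicates 1, 2 and 3. The fit to the 6 arrays of these groups alone gave 51, in which Cd36, Fabp4, Txnip and Ccng1 still passed.

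Of 25 agonist targets 5 rose with MRL24 and none fell, namely Cd36, Fabp4, Acaa1b, Angptl4 and Lpl, and 11 rose when adjusted over the list alone. Acaa1b rose by 0.68 (SE 0.13) and Lpl by 0.25 (SE 0.06). Lpl missed the threshold without wild-type replicate 3 (0.055) or MRL24 replicate 1 (0.0613), 2 (0.0738) or 3 (0.116). The list shifted up (camera adjusted p = 3.26e-05), with adjusted p = 0.148 with an estimated correlation. Of the 13 Ser273 genes 6 rose by either adjustment, which is again not independent evidence (camera adjusted p = 1.48e-05). Cyp2f2 read 705 ± 4.7, Nr1d1 2443 ± 197 and Acly 5213.5 ± 75.2, against 538.5 ± 39.7, 1877 ± 166 and 3990.5 ± 395 in untreated cells. In the fit to these 6 arrays alone Acaa1b (0.0511), Cyp2f2 and Nr1d1 (0.0506 each) missed the threshold, as Acly did with the mean of all probe sets (0.0920). The Ser273 shift was the 1 of 4 list shifts with MRL24 that held with an estimated correlation (adjusted p = 0.0477).

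Genes of oxidative phosphorylation, the respiratory chain and ATP synthase, were lower with MRL24: 9 of 61 fell and none rose, or 29 fell and 2 rose when adjusted over the list alone. Their median log2 change was -0.14, or -0.08 without untreated wild-type replicate 2, and 55 of 61 lay below 0 (camera adjusted p = 6.58e-12, but adjusted p = 0.423 with an estimated correlation). Ndufa4, a small subunit of the chain, fell from 3353.5 ± 308 to 2644 ± 126 (adjusted p = 0.00838, 0.0521 without MRL24 replicate 3 and 0.0506 in the fit to 6 arrays alone). Untreated wild-type replicate 2 held the highest mean level of this list, 0.146 above the mean of the 12 arrays on the log2 scale, against -0.016 and -0.041 on the other untreated arrays. The 37 proteasome subunit genes, which were not a list fixed for testing, had a median of -0.09 with MRL24, or -0.06 without that array, and 2 of them fell. Hypoxia genes shifted up (camera adjusted p = 0.00339, with adjusted p = 0.423 with an estimated correlation), with 1 of 17 higher and 1 lower, or 6 and 1 when adjusted over the list alone. The stress gene Ndrg1 was higher by 0.15 and carbonic anhydrase 9 (Car9), a classic hypoxia target, lower by 0.69. Both calls were lost without wild-type replicate 2 (0.078 and 0.127), MRL24 replicate 2 (0.0794 and 0.0839) or MRL24 replicate 3 (0.13 and 0.139), and that of Ndrg1 without MRL24 replicate 1 (0.0769).

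**Figure D2:**
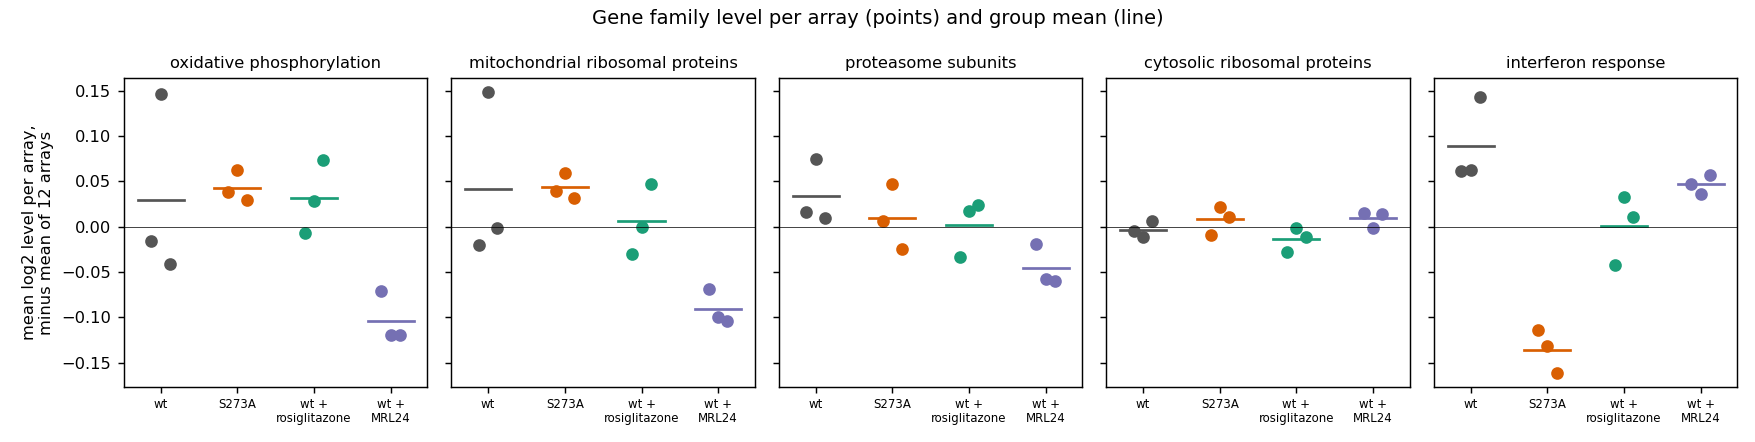
Mean log2 level per array of 5 gene families, minus the mean of all 12 arrays (vertical axis), with 1 point per array and a line at the group mean (n = 3). The MRL24 arrays were lowest for the 61 oxidative phosphorylation and 74 mitochondrial ribosomal genes, and 2 of them for the 37 proteasome subunit genes, where untreated replicate 2 was highest (0.075), the S273A arrays for the 20 interferon response genes, and the 43 cytosolic ribosomal genes stayed within 0.03 of 0.

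Rosiglitazone and MRL24 were then compared directly, at matched dose and time. Cd36 was 3.37-fold higher with rosiglitazone than with MRL24 (log2 difference 1.75, SE 0.08, adjusted p = 2.73e-09, n = 3), Acaa1b 3.09-fold and Angptl4 1.93-fold (adjusted p = 3.09e-06 and 2.73e-09). Fabp4 was higher by 0.71, with a 95% interval of 0.61 to 0.81, Pdk4 by 0.72, Lpl by 0.58 and Plin2 by 0.49. The transcriptional coregulator Cited1 read 957 ± 78.8 against 379 ± 17.1, the protease inhibitor Serpinb2 1636 ± 93.7 against 892 ± 32.6 and the growth hormone-releasing hormone gene Ghrh 1499 ± 97.7 against 888 ± 23.5. Lower with rosiglitazone were Cxcl5 (-0.59, SE 0.10), the stromelysin Mmp10 (-0.46, SE 0.05) and thrombospondin 1 (Thbs1, -0.41, SE 0.06).

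For other genes no difference between the ligands was detected. The difference was 0.04 for Cyp2f2 (95% interval -0.10 to 0.19), 0.11 for Nr1d1 (-0.03 to 0.25) and 0.06 for Txnip (-0.01 to 0.14), 3 genes that rose with both ligands. It was 0.01 for Selenbp1 (-0.12 to 0.15) and -0.02 for Pparg (-0.24 to 0.19).

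In limma's test 229 of 9154 genes differed between the ligands, 129 higher with rosiglitazone and 100 higher with MRL24, 6 of them by over 2-fold. After setting all arrays to the same median, 150 of 215 were higher with rosiglitazone and 65 lower. For 25.2% of the genes the groups did not overlap, where chance gives 10%. The count was 480 without wild-type replicate 2, 114 and 101 without rosiglitazone replicates 2 and 3, and 118, 96 and 104 without MRL24 replicates 1, 2 and 3. It was 132 without the mean trend in the variance, 546 in the fit to the 6 ligand arrays alone and 637 with array weights.

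Of 25 agonist targets 10 were higher with rosiglitazone and none lower, by either adjustment (camera adjusted p = 6.55e-14). Of 25 fatty acid oxidation genes 11 were higher, or 15 when adjusted over the list alone, among them Hadhb (0.44, SE 0.06) and Acaa2 (0.32, SE 0.06), with camera adjusted p = 8.03e-14. Of 23 tricarboxylic acid cycle genes 3 were higher by either adjustment, namely Pdk4, Idh3a (0.42) and Pcx (0.41), with camera adjusted p = 6.15e-05. Of the Ser273 genes 4 were higher, or 6 with 1 lower when adjusted over the list alone, with Peg10 at 1.01 and the amyloid precursor-like protein Aplp2 at 0.41 (camera adjusted p = 1.65e-05). As above, that list is not independent evidence. These 4 shifts held with an estimated correlation (adjusted p = 0.00705, 0.00541, 0.0145 and 0.0145).

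Oxidative phosphorylation genes were higher with rosiglitazone than with MRL24, 4 of 61 over all genes and 22 when adjusted over the list alone, with a median difference of 0.13 (camera adjusted p = 1.21e-17, but adjusted p = 0.228 with an estimated correlation). Cytochrome c (Cycs), the electron carrier of the chain, read 9199 ± 352 with rosiglitazone and 6008 ± 133 with MRL24. Weaker shifts were upward in fatty acid and triglyceride synthesis (2 of 20 higher, 3 over the list alone) and in lipid droplet genes (2 of 12 by either adjustment), and downward in extracellular matrix genes (2 of 32 lower, or 7 lower and 2 higher when adjusted over the list alone). Their camera adjusted p of 0.0243, 0.0213 and 0.0243 became adjusted p = 0.241, 0.43 and 0.526 with an estimated correlation. The first was lost without rosiglitazone replicate 3 (0.0601) or without the filter (0.0505) and the second without rosiglitazone replicate 2 (0.102). The third was lost without rosiglitazone replicates 1 (0.0667) or 3 (0.0557) or MRL24 replicate 3 (0.0729), and after median scaling (0.0761).

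**Figure D3:**
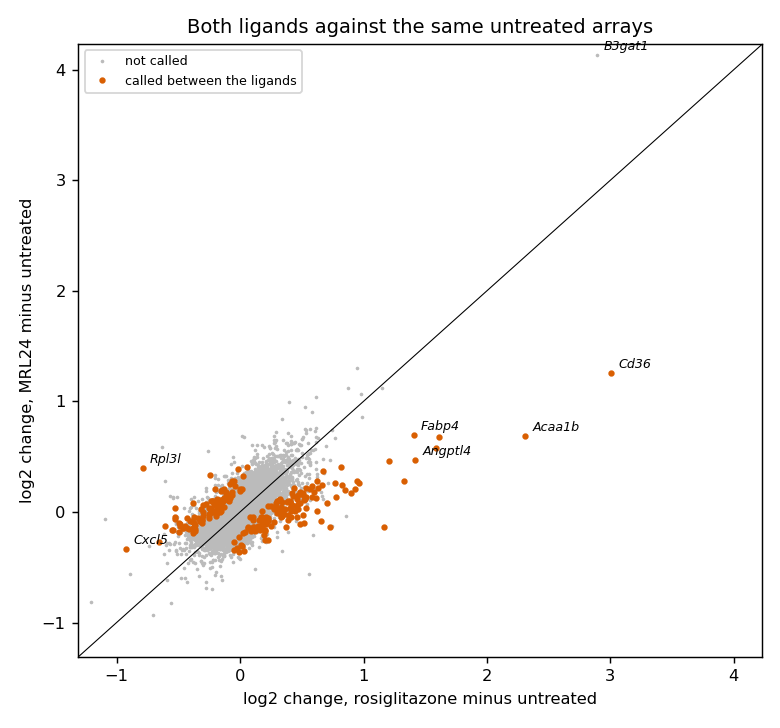
Log2 change with MRL24 (vertical axis) against log2 change with rosiglitazone (horizontal axis), both relative to the same untreated arrays, with 1 point per gene and a line of equal change. Orange points mark the 229 genes that differed between the ligands; Cd36 lies at 3.0 with rosiglitazone and 1.25 with MRL24, and Acaa1b at 2.31 and 0.68.

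**Figure D4:**
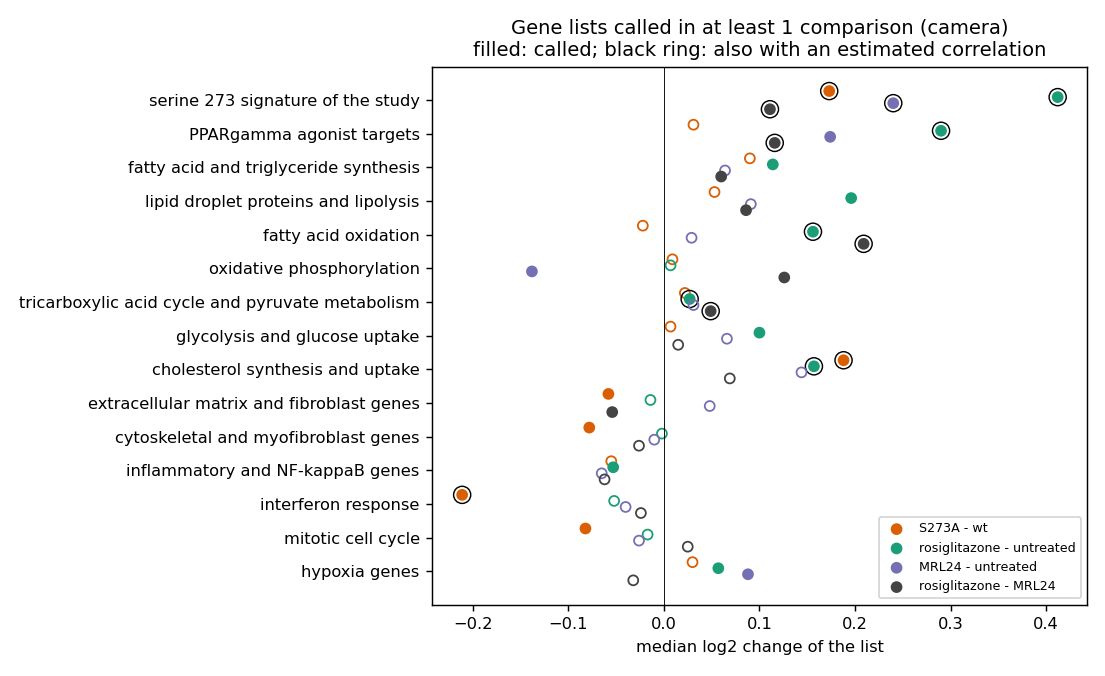
Median log2 change (horizontal axis) of each gene list that shifted in at least 1 comparison (vertical axis), with 1 point per comparison. Filled points passed the camera test and ringed points also passed with an estimated correlation, as for interferon response genes at -0.21 with S273A.

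Because every untreated comparison used the same 3 wild-type arrays, shared changes were set against simulations of unchanged groups. Cd36, Cyp2f2, Nr1d1 and Txnip rose in all 3 comparisons, and Bcl2l11, Bst2 and Ccl2 fell in all 3. In the fit to 6 arrays alone Ccl2 missed the threshold with S273A (0.0581). Bst2 and Ccl2 missed the threshold with MRL24 without MRL24 replicate 1 (0.0589 and 0.0621) or 3 (0.0549 and 0.0621), and Bst2 without wild-type replicate 2 (0.0581). Bcl2l11 probe sets differed in sign with MRL24, from -0.35 to 0.18. In total 29 genes rose and 48 fell in all 3, against 0.23 and 0.44 for independent lists of these sizes, and 2 changed in mixed directions. Unchanged groups were simulated against those arrays in 3 ways, 100 draws each, of which all but the first were added after its values were seen. Median calls per comparison were 0 to 4, but single draws reached 822, 255 and 26 in the order of the simulations. In the first, 1 of 100 draws gave as many calls as observed with rosiglitazone and 1 as many as with MRL24, and no draw did so with S273A or in the other simulations. At most 10 genes were called in 1 direction in all 3, and most draws had too few calls to set beside 77. Lists of the observed lengths, taken from each draw by smallest p after these values had been seen, shared a median of 40, 52 and 190 genes in 1 direction. They shared 77 or more in 30, 34 and 100 of the 100 draws, and in the last simulation the lowest draw shared 163. For lists of these lengths, 77 was therefore not more than unchanged groups gave. Unchanged groups seldom called so many genes, and the matched lists treat every listed gene as noise. They cannot say how many of the 77 came from the shared arrays. The 77 genes became 107, 30 and 123 without wild-type replicates 1, 2 and 3.

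S273A and rosiglitazone shared 189 genes in 1 direction (51 higher, 138 lower) and 18 in opposite directions, Angptl4 and Pdk4 among the latter, against 7.1, 19.2 and 25.1 for independent lists. S273A and MRL24 shared 104 (40 higher and 64 lower, against 6.2 and 10.5), which became 162, 38 and 158 without wild-type replicates 1, 2 and 3, and 4 went in opposite directions (19.1). Rosiglitazone and MRL24 shared 208 (116 higher and 92 lower, against 10.9 and 8.8), and none of their common genes went in opposite directions, against 20.0 for independent lists. Lists of the observed lengths from unchanged groups shared a median of 140 to 274 genes in 1 direction for S273A and rosiglitazone, 108 to 238 for S273A and MRL24 and 128 to 260 for the ligands. The observed numbers were reached in 37 to 100, 52 to 100 and 19 to 100 of 100 draws.

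Over all 9154 genes the changes with S273A and rosiglitazone correlated at r = 0.478 and those with S273A and MRL24 at r = 0.474, where simulated unchanged groups gave mean r of 0.478 to 0.582 and 0.466 to 0.601. For the ligands r was 0.68 against 0.466 to 0.615. Genes are not independent replicates, and shared arrays raise r with no effect at all. The covariance was 0.0145 for S273A and rosiglitazone, 0.0141 for S273A and MRL24 and 0.0224 for the ligands. The simulations that left the smallest excess gave 0.00866 each, leaving 0.00586, 0.00539 and 0.0137. Covariances as large came in 7, 5 and 2 of 100 draws in the simulation least favourable in that respect, which drew residual arrays with replacement and can repeat an array. With residual arrays permuted they came in 0, 1 and 0 of 100 draws. From the wild-type variance alone the excess was 0.00581, 0.00534 and 0.0137. Without wild-type replicate 2 these became 0.00368, 0.00084 and 0.00777, so the second rested on that array. With 3 untreated arrays the controls could not be split into parts of at least 2, and part of each excess may come from them.

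Of the 652 genes that changed with S273A, 416 were called with neither ligand, which does not show that they were unchanged. The direct tests found 254 of the 652 to differ between S273A and rosiglitazone cells and 298 between S273A and MRL24 cells. Among all 9154 genes 805 and 845 differed. The same S273A arrays gave the 652 calls and entered both direct tests, so these counts are not independent of those calls.

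The other lists showed no shift in camera's test in any of the 4 comparisons. The test fry asks whether the genes of a list move on balance one way, without comparing them with other genes. It called 10 of 29 lists with S273A, 12 with each ligand and 10 between the ligands, where camera called 6, 10, 4 and 8. Of 24 thermogenic genes only 11 could be tested, and none of these was called (lowest camera adjusted p = 0.393). Limma's unadjusted p was under 0.05 for 2 of the 11 with S273A, 1 with rosiglitazone, 5 with MRL24 and 0 between the ligands. That list rose on balance with MRL24 in fry's test (adjusted p = 0.0305) and was lower with rosiglitazone than with MRL24 (0.0312). Of 17 adipokines, 4 were higher and 4 lower with S273A, among them Rarres2 and angiotensinogen (Agt) higher and Fstl1 lower. There were 2 and 2 with rosiglitazone, where fry called a rise (adjusted p = 0.00225), and 2 higher and 1 lower both with MRL24 and between the ligands.

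Of 17 adipocyte transcription factors, 1 fell with S273A, 2 fell with rosiglitazone, 1 rose with MRL24 and 2 were lower with rosiglitazone than with MRL24. Egr2 fell with S273A, and also with rosiglitazone by 0.33 (adjusted p = 0.0447). The latter call was lost without wild-type replicate 1 (0.132) or 2 (0.122), S273A replicate 1 (0.0551), 2 (0.0568) or 3 (0.0507), rosiglitazone replicate 2 (0.173) or 3 (0.114), or MRL24 replicate 1 (0.0537) or 3 (0.0586), and in the fit to 6 arrays alone (0.103). Cebpd fell with rosiglitazone (-0.49, SE 0.06), although a second probe set changed by -0.01. Cebpb rose with MRL24 by 0.21 (adjusted p = 0.0206), a call lost without wild-type replicate 2 (0.0639) or MRL24 replicate 1 (0.0624), 2 (0.0797) or 3 (0.0684), and in the fit to 6 arrays alone (0.0751).

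Circadian genes gave 2 higher and 2 lower of 16 with S273A, 2 higher with rosiglitazone and 3 higher with MRL24, where fry called a rise (adjusted p = 0.0136). None differed between the ligands in limma's test, with unadjusted p under 0.05 for 2. Glucocorticoid response genes gave 1 higher and 3 lower of 18 with S273A, 4 and 3 with rosiglitazone, 2 and 0 with MRL24, and 2 and 3 between the ligands. Fry called this list lower with S273A (adjusted p = 0.00705), higher with each ligand (1.2e-04 with rosiglitazone and 0.0176 with MRL24) and higher with rosiglitazone than with MRL24 (0.0245). Its members Angptl4 and Pdk4 are also on the list of agonist targets. Unfolded protein response genes gave 2 higher and 3 lower of 22 with S273A, where Atf3 rose by 0.40 and Dnajb9 fell by 0.28. They gave 1 and 2 with rosiglitazone, 1 and 1 with MRL24 and 0 between the ligands, where limma's unadjusted p was under 0.05 for 6. Heat shock genes had at most 1 of 13 changed in any comparison, oxidative stress genes at most 2 of 16, with a fall in fry's test with rosiglitazone (adjusted p = 0.00579) and a lower level than with MRL24 (0.0337), and p53 targets at most 2 of 18, Ccng1 being higher with S273A (0.52, SE 0.08).

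With S273A, 4 of 5 tested macrophage markers lay above 0 and Cd68 was the 1 that rose, over all genes and over the list alone. The list missed the threshold in camera's test (adjusted p = 0.0602, and 0.271 with an estimated correlation) and passed it in fry's (adjusted p = 0.00249). With MRL24 no macrophage marker changed, 1 of 5 lay above 0 and fry's adjusted p was 0.0447 for a fall (camera adjusted p = 0.25). Outside that list Cybb, an oxidase subunit of phagocytes, also rose with S273A, from 71.1 ± 9.7 to 126 ± 6.1 (log2 change 0.71, SE 0.17, adjusted p = 0.0158). That call was lost without S273A replicate 3 (0.0578) and in the fit to 6 arrays alone (0.0576). The mast cell and basophil protease Mcpt8 rose from 140.1 ± 27.1 to 226 ± 26.7 (0.64, SE 0.18, adjusted p = 0.0436). Its call was lost without wild-type replicate 1 (0.127) or 2 (0.103), S273A replicate 1 (0.135), 2 (0.0611) or 3 (0.122), rosiglitazone replicate 1 (0.0561), or MRL24 replicate 1 (0.0592) or 2 (0.0548). Of 5 endothelial markers the receptor Tek rose with S273A by 0.49, a call lost without wild-type replicate 2 (0.0752) or S273A replicate 2 (0.0624) or 3 (0.103). Of 3 epithelial markers Krt18 fell (-0.46, SE 0.09) and Krt19 rose (0.30, SE 0.07) with S273A by either adjustment, the call of Krt19 being lost without S273A replicate 2 (0.0721). Krt18 also rose with rosiglitazone against untreated cells by 0.37 (adjusted p = 0.0143), a call lost without rosiglitazone replicate 2 (0.0568) or 3 (0.0561), and was higher with rosiglitazone than with MRL24 by 0.51. It was the 1 epithelial marker higher with rosiglitazone, or 1 of 2 when adjusted over the list alone. Over all genes, none of 5 skeletal muscle, 5 chondrocyte, 3 osteoblast or 6 neural markers changed in any comparison (unadjusted p under 0.05 in limma for 1, 3, 5 and 1 of these 19 in the order S273A, rosiglitazone, MRL24 and between the ligands). When adjusted over the list alone, 1 chondrocyte marker was higher with MRL24, 1 osteoblast marker lower with rosiglitazone and 1 higher with MRL24, and 1 neural marker higher with rosiglitazone. The chondrocyte list rose on balance with MRL24 in fry's test (adjusted p = 0.0176, camera adjusted p = 0.126).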

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

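The counts over splits of the arrays, the simulations of unchanged groups after the first, the use of simulations and of lists of matched length for the number of shared genes, the values without single arrays for shared genes and gene families, the proteasome values and the direct contrasts of the ligand groups used as tests were chosen after the results were seen. The spike-in and ribosomal tests and the single-array test of the interferon genes were aimed at patterns already seen. They were chosen before their own values were known.

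Probe sets without a single gene symbol, which no comparison used, also changed: 97 with S273A, 122 with rosiglitazone and 107 with MRL24. With S273A these were 41 of 497 tested probe sets with several symbols and 56 of 807 not named here.

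For each comparison, 3 against 3 arrays make 10 splits, too few for a share under 0.05. The real split gave 652, 721, 503 and 229 genes for S273A, rosiglitazone, MRL24 and the difference between the ligands, and was the 1 split of 10 with as many each time. Other splits mix arrays of both groups, so a difference between the groups widens their spread and lowers their counts. The highest of these splits gave 1, 1, 0 and 0. The highest of 100 draws of simulated unchanged groups gave 252, 822, 603 and 111 in the simulation with the most calls. In that simulation 0, 1, 1 and 0 of 100 draws gave as many genes as observed.

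S273A, rosiglitazone and MRL24 changed 77 genes in 1 direction, or 107, 30 and 123 without wild-type replicates 1, 2 and 3. Unchanged groups simulated against the same arrays had a median of 0 to 4 calls per comparison, with up to 822 in 1 draw, and lists of the observed lengths taken from them shared 77 or more genes in 30, 34 and 100 of 100 draws. Covariances as large as observed came in up to 7, 5 and 2 of 100 draws for the 3 pairs of comparisons. The level of the spike-in controls, through its slope within groups, gave 7.9% of the difference (SE 6.1). The 77 genes were selected for large differences between groups and small spread within them. That selection lowers this share, so it cannot decide the question. A hybridization difference stays open, as do noise of the shared untreated arrays, replicate 2 in particular, and a handling difference common to them. So does a common action of the receptor form and the ligands, and with 1 set of controls these cannot be told apart.

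Oxidative phosphorylation genes had a median log2 change of -0.14 with MRL24, or -0.08 without wild-type replicate 2. Mitochondrial ribosomal genes changed by -0.148 (SE 0.019) and proteasome subunits by -0.094 (SE 0.018), or by -0.086 and -0.059 without that array. Of 37 proteasome genes, 29 had a lower mean level with MRL24 and 2 were called lower in limma's test. The proteasome family was chosen after the results were seen and was not tested as a list. Whether the lower levels reached beyond mitochondrial genes therefore stays open. They were not general among mitochondrial genes. The tricarboxylic acid cycle and fatty acid oxidation lists had medians of 0.031 and 0.029 with MRL24. Each had 1 gene called higher and 0 lower (camera adjusted p = 0.714 and 0.721). Cytosolic ribosomal genes changed by 0.025 (SE 0.008), 0.008 and 0.039 without wild-type replicates 2 and 3, and -0.018 after quantile normalization or median scaling, which argues against short abundant transcripts in general, and the oxidative phosphorylation list was 0.126 higher with rosiglitazone than with MRL24, which argues against the untreated arrays as the whole source. How near the cytosolic ribosomal genes lay to the array maximum, where intensities may understate a change, was not checked. These errors treat genes as independent. With an estimated correlation the oxidative phosphorylation list had camera adjusted p = 0.423 with MRL24 and 0.228 between the ligands. What the lower families have in common stays open, as does a difference in the culture or handling of the 3 MRL24 arrays.

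Interferon response genes had a median log2 change of -0.21 with S273A. The ligand groups lay above S273A by 0.155 and 0.168, which argues against the untreated arrays as the whole source. Against those arrays the list's median was -0.052 with rosiglitazone and -0.04 with MRL24 (fry adjusted p = 0.00953 and 0.0634, both lower). The highest camera adjusted p without 1 of the 6 arrays was 0.00228, which argues against a single array. An effect of S273A and a difference between the separately prepared cell populations stay open, since each form was present in 1 set of cells as far as the labels say.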

How the results depend on the processing

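Of the simulations behind the excess covariance, those after the first were chosen once its values had been seen. Of 323 called values of named genes, 150 kept their call in every setting. Fitting only the 2 groups compared gave 238 genes with S273A, 355 with rosiglitazone, 51 with MRL24 and 546 between the ligands. Such a fit has fewer arrays to estimate the spread, which alone would not raise the count between the ligands from 229. It also takes the spread from those groups only. The residual SD was 0.122 to 0.148 on untreated arrays and 0.095 to 0.111 on ligand arrays. The main fit used 1 spread for all groups, and how far this moved the counts was not tested. With MRL24 there were 225 genes without the filter and 162 without the mean trend. Between the ligands there were 132 without the mean trend and 637 with array weights; the cause was not tested. Leaving out 1 array gave 390 to 632 genes with S273A, 384 to 759 with rosiglitazone, 76 to 818 with MRL24 and 96 to 480 between the ligands. With an estimated correlation the shifted lists numbered 3, 5, 1 and 4 in place of 6, 10, 4 and 8. Leaving out 1 array gave 3 to 7, 10 to 10, 4 to 5 and 6 to 8 lists. The excess covariance ranged over single arrays from 0.00368 to 0.00729 for S273A and rosiglitazone, 0.00084 to 0.00835 for S273A and MRL24 and 0.00777 to 0.01755 for the ligands. With the mean of all probe sets the sign turned for Ddx17 (0.283) and Timp3 (0.003) with rosiglitazone, for Nr1d2 (0.446), Timp3 (0.078) and Pdgfra (0.083) with MRL24, and for Decr1 between the ligands (-0.023). Vegfa with S273A ranged from -0.287 to 0.111 over single arrays, the latter without wild-type replicate 2. The probe set used changed by -0.249 and a second one, almost as bright (mean log2 12.54 against 12.58), by 0.226. The brightest probe set was picked again without each array, so this range may reflect a switch between them, which was not checked. A replicate block gave 538, 608, 350 and 174 genes. Replicate numbers did not pair the arrays, since 1 of 18 pairs with the same number had a residual correlation over 0.1. Signals near the floor limit what can be seen of dim genes.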

Other observations

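The direct contrasts of the ligand groups with S273A were chosen after the results were seen and were not among the comparisons fixed beforehand. S100a8 read 1323 ± 20.0 in S273A cells, 532 ± 44.6 with rosiglitazone and 447 ± 25.3 with MRL24 (intensity, n = 3). Cd68 read 869.7 ± 11.4, 496 ± 21.3 and 482 ± 28.9, and Postn 246 ± 25.6, 404.5 ± 21.4 and 454 ± 16.2. In limma's test rosiglitazone minus S273A was -1.29 for S100a8 (adjusted p = 6.02e-07), -0.79 for Cd68 (2.11e-06) and 0.69 for Postn (6.18e-05), and MRL24 minus S273A was of the same sign for each. Selenbp1 was lower by 0.36 with rosiglitazone than in S273A cells (adjusted p = 0.00181). These genes had been called with S273A on the same S273A arrays, so the direct contrasts are not independent of that call.

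The spike-in control BioB, added to the hybridization, read 1141 ± 121 on untreated arrays, 1052 ± 42.4 on S273A, 982 ± 102 on rosiglitazone and 903 ± 56.5 on MRL24 arrays (two-sided exact p = 0.3, 0.1 and 0.1 against untreated arrays, where 0.1 is the smallest that 3 against 3 arrays can give). BioC read 2716 ± 246, 2498 ± 107, 2466.5 ± 241 and 2252 ± 117 in the same order (exact p = 0.3, 0.5 and 0.1).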
